A study of Homo sapiens with 6 samples.

How the data were processed

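RNA sequencing was available for 6 libraries of human prostate cancer cells, 1 for each combination of 2 cell lines and 3 treatments. LNCaP is an established, androgen-responsive line. The other line carries the name BicR in the labels, which describe it only as prostate cancer and do not say how it was derived. Per the labels' protocols, both lines were kept for 3 days in phenol red-free medium with 2.5% stripped serum, which is low in steroid hormones, and then received ethanol vehicle, 10 nM dihydrotestosterone (DHT, an androgen) or 1 µM bicalutamide (an antiandrogen) over 24 h. Total RNA was isolated with ISOGEN and sequenced on the SOLiD 3 Plus platform, per the labels' protocols.

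The deposited table held raw counts per gene symbol for each library and, beside them, RPKM values made by the authors, per the file headers. The genome build was hg19, per the submitters' processing notes. The aligner, the counting tool, the gene annotation and whether counting used strand are not given in the sources used here. RPKM, which the authors scaled to gene model length and sequencing depth, was used only as an alternative scale and to derive relative gene length, as counts divided by RPKM. The series' design text speaks of small RNAs, while the table lists gene symbols. Of its 21512 rows, 2988 were at 0 in every library, 27 carried date-like names left by a spreadsheet, and 0 names were duplicated. No coordinates are reported because the table gave none.

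Total counts per library ran from 42162723 to 55917016. Genes with a mean of at least 20 counts over the 6 libraries were tested, which left 13885. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3). Levels are given as CPM, counts relative to the scaled library size, computed here from the deposited counts. Ratios of counts between a pair of libraries carry exact 95% intervals that condition on the summed count. A count of 0 was set to a floor of 3 counts per library, 0.0553 to 0.0715 CPM. Intervals and floors cover counting error only, not variation between cultures.

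With 1 library per line and treatment, differences within a line have no replicate check. They were described on the log2(CPM + 1) scale, which understates the change of low genes, and a gene was counted when the difference reached 2-fold. For gene lists within a line the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Treatment effects over both lines, and the difference of the lines over treatments, were tested with an additive model (cell line plus treatment) and edgeR's quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment at 0.05. In this model the disagreement between the lines is the error, so a response in 1 line alone counts as noise. It left 2 residual degrees of freedom, and the fit gave 6.8 prior degrees of freedom. Nothing in the labels says that any library pooled or repeated cultures, so the p-values measure only the spread between these libraries. No interaction of line and treatment could be tested.

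Gene lists, 26 with at least 5 tested members, were written before the data were examined, as were the tests, the rule for named genes and all alternatives but those said below to be later. They cover androgen response, steroid and lipid metabolism, the cell cycle, stress responses, translation and respiration, and markers of other cell types. They were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, with an estimated correlation and, beside these, with fry. Benjamini-Hochberg adjustment ran over the lists of a contrast. The estimated correlation came from the residuals, which hold the disagreement between the lines, and rested on the 2 residual degrees of freedom. With it 0 lists passed in any contrast, so a list that failed it was not thereby shown to be unchanged. All adjusted p-values given for single genes are edgeR's unless another tool is named, and standard errors (SE) are on the log2 scale. Comparisons against a shared ethanol library were set beside 20 simulations of unchanged libraries, with the spread of the additive fit.

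Genes were named by rule. Over both lines these were the 6 highest and 6 lowest log2 fold changes among genes that passed with the same sign in every matched pair, filled up, where fewer did, with genes that did not pass, ranked by the smaller of the differences in the matched pairs. Within a line they were the 4 highest and 4 lowest differences, and for each list passing camera the 3 members that changed most in its direction. Genes fixed in advance, named whatever their result, included KLK3, KLK2, TMPRSS2, FKBP5, NDRG1, UGT2B15, UGT2B17, OPRK1, NR3C1 and TET2. Not every gene picked by these rules is reported here. Reads of near-identical genes (TUBA3D and TUBA3E, the UGT2B family, HSPA6 and its pseudogene, ribosomal proteins) and of genes inside other genes (small nucleolar RNAs in their hosts, TARP in a T cell receptor locus) may have been divided between copies, so their values are uncertain.

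The fit was tested on simulated data drawn for the DHT contrast over both lines, with the 13885 real gene means and the spread of the real fit. Changed genes were drawn only from those with a higher mean CPM, and both lines received the same fold. The percentages below therefore do not cover low genes or responses of unequal size in the lines. Over 3 simulations it called 63.67% of genes changed 2-fold and 100% of those changed 4-fold, with a mean of 8.333 false calls, and 0 genes when none was changed. In the unchanged simulations a mean of 71 genes still reached 2-fold between the LNCaP libraries. The alternatives tried were other pseudocounts, count minimums, fold thresholds and scalings, limma, DESeq2 1.42.0, fewer libraries in the fit, each library left out in turn and, for the difference of the lines, no treatment term. Chosen after seeing the data were RLE size factors, removal of a gene length trend, the authors' RPKM, and the bicalutamide or DHT libraries in place of ethanol.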

Results

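The transcriptomes of LNCaP and BicR cells were compared after 24 h of ethanol vehicle, DHT or bicalutamide, 1 library for each line and treatment. Total counts were 54380474, 55917016 and 50871634 for LNCaP under ethanol, DHT and bicalutamide, and 49460929, 42162723 and 47185123 for BicR in the same order. Between 16756 and 17062 genes had counts in a library. The BicR ethanol and bicalutamide libraries were the closest pair, with a correlation of 0.998 across genes and a chi-square per degree of freedom of 10.5, against 87.2 to 375 in every other pair, so no library was taken as a repeat count of another. LNCaP bicalutamide correlated with BicR ethanol at 0.9861 and with LNCaP ethanol at 0.9813. In the LNCaP ethanol library the endoplasmic reticulum chaperone gene HSPA5 alone took 0.79% of counts, against 0.131% to 0.164% in the other 5 libraries. Ribosomal protein genes took 5.44% and 5.99% of counts in LNCaP ethanol and DHT, and 3.54% to 3.78% in the other 4 libraries.

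The first comparison asked which transcripts DHT changed in both lines. KLK2 and KLK3, which encode secreted kallikreins (KLK3 is prostate-specific antigen), rose by 2.88 (SE 0.29) and 1.93 (SE 0.26) on the log2 scale, with adjusted p = 0.0135 and 0.033, and both were higher in 2 of 2 lines. The membrane serine protease gene TMPRSS2 rose by 2.77 (SE 0.29, adjusted p = 0.0135). In all, 22 genes rose and 1 fell among 13885 tested, each with the same sign in both lines.

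The counts behind the highest fold changes were low without DHT. CCDC141 had 0 counts in LNCaP ethanol and 28 in LNCaP DHT, at least 8.59-fold higher against the floor of that library, and 1 and 588 counts in BicR, a ratio of 730 (95% counting interval 131 to 28900); its adjusted p was 0.00441. STEAP4, a metalloreductase gene, went from 11 to 358 counts in LNCaP, a ratio with a counting interval of 16.5 to 60.6, and from 8 to 5668 in BicR, a ratio of 880 (446 to 2040), with adjusted p = 0.025. NNMT, which encodes nicotinamide N-methyltransferase, had 0 and 46 counts in LNCaP, at least 14.1-fold higher, and 8 and 240 in BicR, a ratio of 37.3 (18.6 to 87.3), with adjusted p = 0.0423. The alpha-tubulin gene TUBA3E rose by 4.71 (SE 0.51, adjusted p = 0.0135), HPGD, which encodes an enzyme that inactivates prostaglandins, by 4.50 (SE 0.54, adjusted p = 0.0229), and PGC, the pepsinogen C gene, by 4.48 (SE 0.51, adjusted p = 0.0168). MAN1A1, which encodes a mannosidase that trims N-glycans in the Golgi, was the gene that fell, by 1.61 on the log2 scale (SE 0.23, adjusted p = 0.0423), from 40.6 to 13.9 CPM in LNCaP and from 18.3 to 5.65 CPM in BicR. The genes that filled the list of lowest changes did not pass: SLC5A1 stood at -1.88 (adjusted p = 0.24), AGT at -1.11 (0.631), PEG10 at -1.42 (0.154), TNC at -2.06 (0.212) and COLEC12 at -1.22 (0.1). Of the remaining genes that rose, named after their values were seen, CHRNA2 rose by 4.31, PLA2G5 by 4.26, TUBA3D by 4.14, CENPN by 3.30, TRPM8 by 2.70, SLC45A3 by 2.45, PMEPA1 by 2.27, KLK15 by 1.84, KLK4 by 1.57 and DUSP4 by 1.39.

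**Figure D1:**
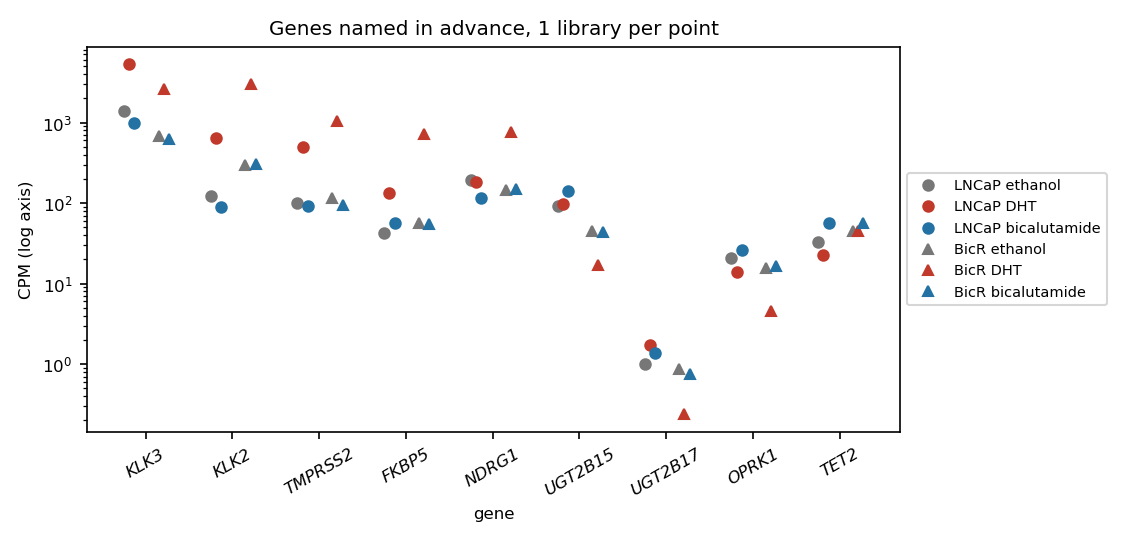
CPM on a log axis for 9 genes named in advance, 1 point per library, circles for LNCaP and triangles for BicR, grey for ethanol, red for DHT and blue for bicalutamide. KLK2 stood at 121, 637 and 88.3 CPM in LNCaP and at 298, 3047 and 302 CPM in BicR under ethanol, DHT and bicalutamide.

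Of the 52 tested members of the androgen-induced list, 13 rose, 0 fell and 39 did not pass; adjusted over the list alone, 36 rose and 1 fell. The median log2 fold change of the list was 1.38, and camera gave adjusted p = 3.25e-95, which became adjusted p = 0.416 with an estimated correlation; the median was 0.73 without BicR DHT. STEAP4 and HPGD led it together with SLC38A4, an amino acid transporter gene at 4.43 that did not pass (adjusted p = 0.136). The luminal prostate epithelium markers, 10 of which are also on the androgen-induced list, had 7 of 22 members rise, 0 fall and 15 not pass, or 9 and 1 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.75e-32, adjusted p = 0.217 with an estimated correlation) and of 0.70 without LNCaP DHT. TARP, read from the T cell receptor gamma locus in prostate cells, rose by 3.07 (SE 0.26, adjusted p = 0.00726) and led this list with KLK2 and TMPRSS2. Among 18 glucocorticoid receptor targets, 4 of them shared with the androgen-induced list, ZBTB16 rose by 2.08 (SE 0.28, adjusted p = 0.0314), 0 fell and 17 did not pass, or 3 rose and 0 fell adjusted over the list alone (median 0.54, 0.34 without BicR DHT, camera adjusted p = 1.1e-11, adjusted p = 0.217 with an estimated correlation). FKBP5, a receptor co-chaperone gene, stood at 2.81 (adjusted p = 0.15) and the kinase gene SGK1 at 2.15 (adjusted p = 0.556).

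None of the 32 androgen-repressed genes passed, over all genes or adjusted over the list alone. Their median was -0.46 (camera adjusted p = 0.000228, adjusted p = 0.779 with an estimated correlation), and it was 0.01 without the BicR DHT library, -0.17 without BicR ethanol, -0.71 without LNCaP ethanol and -0.96 without LNCaP DHT. SI, which encodes sucrase-isomaltase, stood at -1.82 (adjusted p = 0.712), LRRN1 at -1.30 (0.714) and DDC, the dopa decarboxylase gene, at -1.18 (1). All 40 mitosis genes had a positive estimate and 0 passed, over all genes or adjusted over the list alone, with NUF2 at 1.30 (adjusted p = 0.958), CDCA3 at 1.25 (0.822) and PLK1 at 1.21 (0.822). The mitosis median was 0.82 (camera adjusted p = 2.42e-22, adjusted p = 0.733 with an estimated correlation), and without the LNCaP ethanol library it was 0.06 with camera adjusted p = 0.844. It was 0.49 without LNCaP DHT, 1.86 without BicR ethanol and 1.30 without BicR DHT. No member passed, over all genes or adjusted over the list alone, in the lists of DNA replication (43 genes, median 0.18), cholesterol synthesis (25, 0.14), fatty acid synthesis (20, 0.08), replication-dependent histones (16, 0.26), basal epithelium markers (7, -0.37) and p53 targets (24, -0.17). Camera gave these lists adjusted p = 0.00938, 0.00938, 0.0357, 0.00938, 0.00118 and 0.00593 in that order, and the lowest adjusted p with an estimated correlation was 0.446. Within LNCaP and BicR the medians were 0.52 and -0.25 for DNA replication, -0.07 and 0.41 for cholesterol synthesis, and 0.00 and 0.28 for fatty acid synthesis. Members with the largest estimates included RRM2 at 0.85, TK1 at 0.69 and TYMS at 0.55 for replication, IDI1 at 0.49 and INSIG1 at 0.49 for cholesterol synthesis, and ACSL3 at 1.59, ELOVL7 at 1.12 and ELOVL5 at 1.03 for fatty acid synthesis, none of which passed.

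Among the other genes named in advance, TET2, which encodes an enzyme of DNA demethylation, stood at -0.27 (SE 0.24, adjusted p = 1). NDRG1 was at 0.924 times its ethanol level in LNCaP (0.898 to 0.95) and 5.21 times in BicR (5.08 to 5.34), with adjusted p = 0.838 over both lines. UGT2B15, a gene for an androgen-glucuronidating enzyme, was at 1.06 times in LNCaP (1.02 to 1.1) and 0.384 times in BicR (0.353 to 0.418), with adjusted p = 0.958. UGT2B17, another such gene, had 50 and 94 counts in LNCaP and 45 and 10 in BicR under ethanol and DHT, with adjusted p = 1. OPRK1, the kappa opioid receptor gene, stood at -1.13 (SE 0.30, adjusted p = 0.48), and NR3C1, the glucocorticoid receptor gene, had 3 to 19 counts per library and was not tested.

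The DHT call depended on single libraries. By edgeR, 111 genes rose and 48 fell without LNCaP ethanol, 144 and 51 without LNCaP DHT, 167 and 106 without BicR ethanol, and 12 and 0 without BicR DHT (553 lower at an unadjusted p under 0.05), while leaving out LNCaP bicalutamide or BicR bicalutamide gave 0 and 0 (322 higher and 337 lower, and 321 and 338, at an unadjusted p under 0.05). Of the 22 genes that rose, all 22 also passed in DESeq2, which called 75 higher and 24 lower, and in each of the fits without LNCaP ethanol, LNCaP DHT or BicR ethanol.

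Within LNCaP, DHT gave 194 genes at least 2-fold higher and 165 at least 2-fold lower than ethanol; there was no test. TXNIP, which encodes a thioredoxin inhibitor, was 20.2-fold higher (95% counting interval 18.7 to 21.9), the centromere gene CENPN 6.74-fold (6.15 to 7.4), STEAP4 16.5-fold to 60.6-fold by its interval, and PGC 11.1-fold (8.34 to 14.9). AGR2, a gene for a protein of the disulfide isomerase family, was at 0.141 times its ethanol level (0.13 to 0.153), HSPA5 at 0.157 (0.156 to 0.158), ODZ4 at 0.0964 (0.0742 to 0.123) and the chemokine receptor gene CCR2 at 0.0941 (0.0691 to 0.126). KLK3 was 3.75-fold higher (3.72 to 3.78), KLK2 5.27-fold (5.13 to 5.41), TMPRSS2 4.96-fold (4.81 to 5.11) and FKBP5 3.07-fold (2.92 to 3.22).

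The androgen-induced list had a median difference of 0.58 in LNCaP, at percentile 100 of random lists, and 19 of its 52 members were at least 2-fold higher. Of the 40 mitosis genes, 39 were at least 2-fold higher (median 1.60, percentile 100). Of the 36 genes of the unfolded protein response and secretory pathway, 17 were at least 2-fold lower (median -0.94, percentile 0). DNA replication genes had a median of 0.52, DNA repair genes 0.42 and the amino acid stress response -0.40. With the LNCaP bicalutamide library in place of ethanol, the medians were 0.09 for mitosis, -0.05 for the unfolded protein response and 0.55 for the androgen-induced list. Androgen-repressed genes had a median of 0.10 against ethanol, with 1 of 32 at least 2-fold lower, and of -0.31 against bicalutamide (percentile 0.01), with 3 of 32 at least 2-fold lower. The 2-fold counts moved with the pseudocount, from 352 and 304 at 0.1 to 78 and 84 at 5.

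In BicR, DHT gave 202 genes at least 2-fold higher and 128 at least 2-fold lower. STEAP4 was 880-fold higher (446 to 2040), the nicotinic receptor gene CHRNA2 42.2-fold (35.4 to 50.6), TRIM49L 28.4-fold (23.4 to 34.8) and the titin gene TTN higher by 4.17 on the log2(CPM + 1) scale. SI was at 0.0813 times its ethanol level (0.0684 to 0.0961), ABCA1, a cholesterol efflux transporter gene, at 0.0871 (0.0712 to 0.106), DDC at 0.13 (0.116 to 0.145) and CBLN2 at 0.147 (0.138 to 0.158). KLK3 was 3.87-fold higher (3.83 to 3.92), KLK2 10.2-fold (10 to 10.4), TMPRSS2 9.03-fold (8.79 to 9.28) and FKBP5 12.6-fold (12.1 to 13.1).

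Of the 52 androgen-induced genes, 38 were at least 2-fold higher in BicR (median 1.76, percentile 100), and of the 32 androgen-repressed genes 13 were at least 2-fold lower and 2 higher (median -0.73, percentile 0). Cholesterol synthesis genes had a median of 0.41, fatty acid synthesis genes 0.28, the unfolded protein response 0.49 and the amino acid stress response 0.42, all at percentile 100. Interferon response genes had a median of -0.27 and DNA replication genes -0.25, both at percentile 0. Mitosis genes had a median of 0.07 at percentile 91.2. Immune cell markers had a median of -0.60 over 5 genes and mesenchymal markers -0.19 over 18. The count of lower genes was 408 with a pseudocount of 0.1 and 55 with 5.

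Set side by side, the DHT responses of the lines correlated weakly across genes (Pearson r = 0.116, Spearman rho = 0.0152 over 13885 genes, which are not independent replicates), and r was 0.189 against bicalutamide. The lines shared 40 genes at least 2-fold higher, where independent lists would share 2.82, and 4 at least 2-fold lower (AGT, MAN1A1, PEG10 and SLC5A1), where independent lists would share 1.52. In opposite directions 5 genes passed 2-fold. Against bicalutamide 35 genes were shared higher (3.12 for independent lists) and 11 lower (1.29), and 1 gene passed 2-fold in opposite directions. Each line was compared with its own ethanol library. Whether the responses differed between the lines could not be tested.

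**Figure D2:**
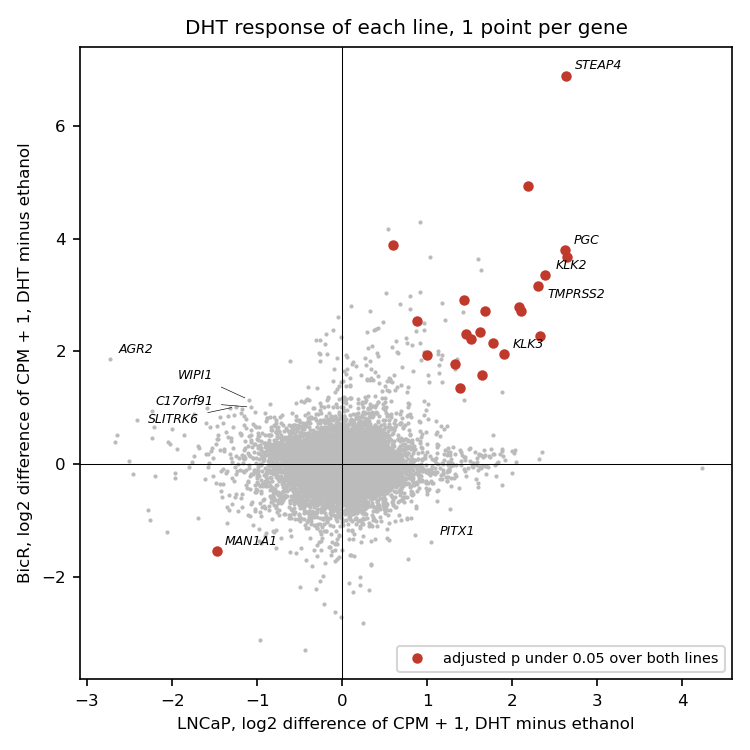
Difference in log2(CPM + 1) between DHT and ethanol for each of 13885 genes, LNCaP on the horizontal and BicR on the vertical axis, with the 23 genes that passed over both lines in red. The red genes lie in the upper right except MAN1A1 in the lower left, and STEAP4 stands at 2.64 in LNCaP and 6.88 in BicR.

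The next comparison asked what the antagonist bicalutamide did in hormone-poor medium. No gene passed over both lines. In LNCaP the androgen targets KLK3 and KLK2 stood at 0.698 times (95% counting interval 0.69 to 0.706) and 0.731 times (0.703 to 0.759) their ethanol level, and in BicR at 0.938 (0.924 to 0.952) and 1.01 (0.991 to 1.04). In BicR no gene differed by 2-fold, while LNCaP had 150 genes at least 2-fold higher and 211 lower. With a pseudocount of 0.1 the counts were 15 and 15 in BicR and 303 and 337 in LNCaP, and with 5 they were 45 and 130 in LNCaP.

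By edgeR's quasi-likelihood test 0 genes rose and 0 fell over both lines, with 52 higher and 89 lower at an unadjusted p under 0.05; DESeq2 and limma also called 0. Leaving out BicR ethanol gave 102 higher and 95 lower, and leaving out any other library gave 0. The genes filled in by rule, ranked by the smaller of the differences in the 2 lines, did not pass: ZNF140 at 0.63, MAOB at 0.73, TRDN at 1.22, C7orf63 at 0.71, SNORD69 at 1.17 and HOXB5 at 0.69, and on the other side KRT75 at -0.88, INCA1 at -0.80, TINAGL1 at -0.77, FAM128B at -0.53, the heat shock gene HSPA6 at -2.17 and LRRC29 at -0.66, each with adjusted p = 0.996.

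Camera passed 11 lists although 0 of their members passed, over all genes or adjusted over the list alone, and the lowest adjusted p with an estimated correlation was 0.709. Mitosis had a median of 0.66 (camera adjusted p = 3.69e-24), led by HMMR at 1.11, DLGAP5 at 0.94 and NUF2 at 0.91. The unfolded protein response had a median of -0.50 (1.48e-14), led by HSPA5 at -1.55, MANF at -1.44 and PDIA4 at -1.38. Without the LNCaP ethanol library these medians were -0.14 and 0.12, and without BicR ethanol 1.71 and -1.03. The mitosis median was 0.19 without LNCaP bicalutamide and 1.21 without BicR bicalutamide. Ribosomal proteins had a median of -0.33 (3.27e-16), with RPLP0 at -0.71, RPL37A at -0.68 and RPL7A at -0.63, and without the LNCaP bicalutamide library the median was -0.05 (camera adjusted p = 0.309), against -0.64 without BicR bicalutamide. The amino acid stress response stood at -0.24 (SLC3A2, ATF3 and DDIT3 lowest), hypoxia and glycolysis at -0.15 (P4HA2, ANKRD37 and NDRG1), cholesterol synthesis at -0.15 (MVD, PMVK and DHCR7) and oxidative phosphorylation at -0.10 (NDUFA1, NDUFB8 and COX4I1). On the higher side were DNA repair at 0.25 (XRCC2, BRCA2 and BLM), androgen-repressed genes at 0.23 (TET2, UGT2B28 and UGT2B10), nuclear receptor coregulators at 0.11 (POU2F1, NCOA2 and HSP90AA1) and prostate long noncoding RNAs at 0.24 (MALAT1 at 1.09, KCNQ1OT1 at 0.54 and TUG1 at 0.28). Most of these medians came from LNCaP. In LNCaP and BicR they were 0.48 and -0.10 for DNA repair, 0.43 and 0.02 for androgen-repressed genes, 0.26 and 0.03 for the coregulators, 0.53 and 0.00 for long noncoding RNAs, -0.53 and 0.08 for the amino acid stress response, and -0.29 and 0.01 for hypoxia and glycolysis, against -0.20 and -0.10 for cholesterol synthesis and -0.14 and -0.10 for oxidative phosphorylation. Androgen-induced genes had a median of -0.02 (camera adjusted p = 0.471).

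Within LNCaP, TXNIP was 7.43-fold higher with bicalutamide (6.84 to 8.07), the small nucleolar RNA SNORD116-29 16.6-fold (11.1 to 26), SNORD44 8.24-fold (6.79 to 10.1) and the mitotic gene HMMR 6.96-fold (5.56 to 8.81). AGR2 stood at 0.0927 times its ethanol level (0.0837 to 0.102), DERL3 at 0.106 (0.0832 to 0.133), HSPA5 at 0.167 (0.166 to 0.168) and MANF at 0.171 (0.165 to 0.177); the last 3 serve protein folding and quality control in the endoplasmic reticulum. Of 40 mitosis genes 38 were at least 2-fold higher (median 1.51), and of 36 unfolded protein response genes 15 were at least 2-fold lower (median -0.86). Ribosomal proteins had a median of -0.59, or -0.33 with the length trend removed. In BicR the extremes of the bicalutamide comparison were SNORD2 at 0.93, SNORD100 at 0.78, SNORD31 at 0.65 and MAOB at 0.64, and C1orf86 at -0.70, NDUFS7 at -0.70, LOC641746 at -0.66 and SNORD47 at -0.65. The BicR medians were -0.08 for androgen-induced genes, -0.18 for mitosis and -0.12 for DNA replication, all at percentile 0.

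In LNCaP the differences of DHT and of bicalutamide from the shared ethanol library correlated at r = 0.456 across genes, against 0.504 in simulations of unchanged libraries, with a covariance of 0.0776 against 0.0622. At least 2-fold higher under both were 92 genes, against 5.25 in the simulations and 2.1 for independent lists, and 84 were lower under both, against 2.15 and 2.51. With 1 ethanol library per line the control could not be split, so part of the excess may come from the shared control. In BicR the covariance was 0.0103, below the simulated 0.0613. The simulated spread was that of the additive fit, where disagreement between the lines counts as error. For BicR the simulations gave 37.6 genes at least 2-fold higher than ethanol, while BicR bicalutamide had 0. That spread was thus too wide for this pair, so the simulated values give no background for unchanged cultures of 1 line.

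**Figure D3:**
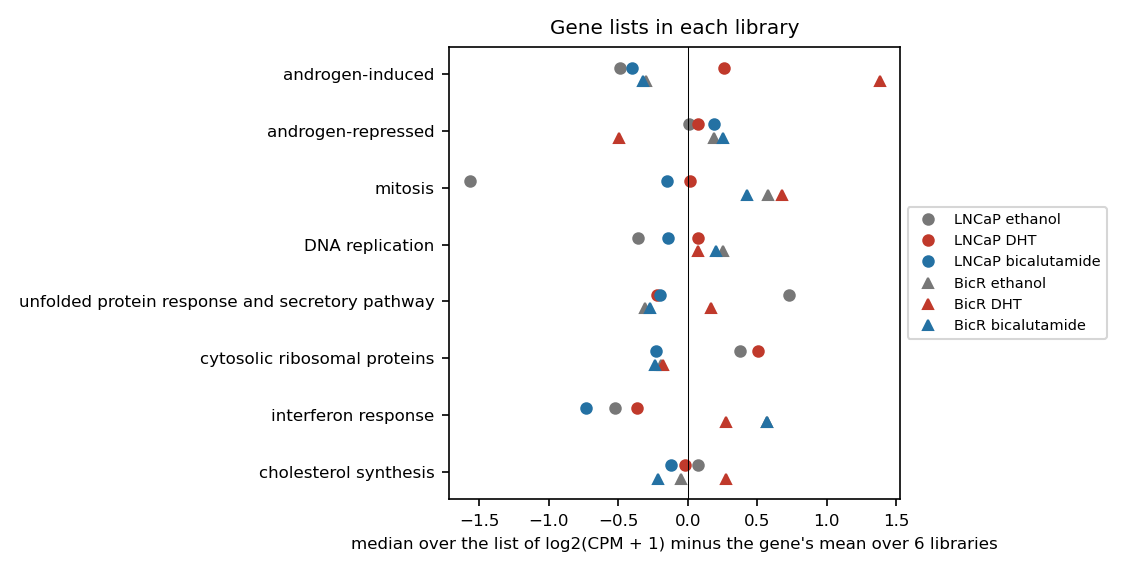
Median over each of 8 gene lists of log2(CPM + 1) minus the gene's mean over 6 libraries, 1 point per library, circles for LNCaP and triangles for BicR, grey for ethanol, red for DHT and blue for bicalutamide. LNCaP ethanol lies at -1.57 for mitosis and 0.73 for the unfolded protein response, and BicR DHT at 1.38 for androgen-induced genes.

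Agonist and antagonist were then compared directly, without the ethanol libraries in the contrast. Under DHT 23 genes rose and 0 fell over both lines. STEAP4 rose by 8.91 (SE 1.03, adjusted p = 0.0164), TUBA3E by 4.70, PGC by 4.60, CHRNA2 by 4.56 and TUBA3D by 4.35, and CCDC141 passed with adjusted p = 0.00543 at 0 to 2 counts under bicalutamide. KLK2 rose by 3.11 (SE 0.29, adjusted p = 0.0122), TMPRSS2 by 2.95 (SE 0.29, adjusted p = 0.0123) and KLK3 by 2.23 (SE 0.26, adjusted p = 0.0173). The genes filled in on the lower side did not pass, with ABCA1 at -2.57 (adjusted p = 0.153), MMP16 at -1.45 (0.0874), DGKH at -1.28 (0.39), AHNAK2 at -1.27 (0.0738), ATP2B1 at -1.15 (0.141) and LRRN1 at -1.65 (0.449).

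Of the 52 androgen-induced genes 13 rose, 0 fell and 39 did not pass, or 37 and 0 adjusted over the list alone (median 1.43, 0.66 without BicR DHT, camera adjusted p = 3.04e-82, adjusted p = 0.441 with an estimated correlation). Of the 22 luminal markers 7 rose and 0 fell, or 9 and 1 adjusted over the list alone (median 0.41, adjusted p = 0.191 with an estimated correlation), led by TARP at 3.13. Among 18 glucocorticoid receptor targets ZBTB16 rose by 2.04 and 0 fell, or 6 and 0 adjusted over the list alone (median 0.67, adjusted p = 0.191 with an estimated correlation), while FKBP5 at 2.59 and SGK1 at 2.18 did not pass. Of the 32 androgen-repressed genes 0 rose and 0 fell, or 1 and 5 adjusted over the list alone (median -0.67, -0.24 without BicR DHT, -0.44 without BicR bicalutamide, -1.0 without LNCaP DHT, camera adjusted p = 4.78e-08, adjusted p = 0.646 with an estimated correlation). No member passed in the other 7 lists that camera called. These were cholesterol synthesis (median 0.35, adjusted p = 0.73 with an estimated correlation, a median of 0.13 with camera adjusted p = 0.263 without BicR DHT and of 0.59 without LNCaP DHT), the unfolded protein response (0.29, CREB3L4 at 1.22, 0.889), the amino acid stress response (0.19, NUPR1 at 0.56, 0.889), oxidative phosphorylation (0.18, COX4I1 at 0.55, 0.889), ribosomal proteins (0.37, RPS19 at 0.92, 0.844), histones (0.38, HIST1H2AE at 0.73, 0.441) and basal markers (-0.27, TRIM29 at -0.86, 0.646). Within LNCaP and BicR the medians were -0.05 and 0.44 for the unfolded protein response, 0.01 and 0.31 for the amino acid stress response, and 0.31 and -0.03 for oxidative phosphorylation. For ribosomal proteins the median was 0.10 without LNCaP bicalutamide (camera adjusted p = 0.0506), 0.16 without LNCaP DHT, 0.60 without BicR DHT, 0.72 without BicR bicalutamide and 0.17 with the length trend removed.

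At an unadjusted p under 0.05, edgeR placed 483 genes higher and 504 lower under DHT than under bicalutamide, and DESeq2 called 89 and 33, all 23 among the former. The edgeR counts were 127 and 61 without LNCaP ethanol, 135 and 62 without LNCaP DHT, 124 and 62 without BicR ethanol, and 0 and 0 without LNCaP bicalutamide (227 and 177 at an unadjusted p under 0.05) or BicR bicalutamide (873 and 696).

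The last comparison asked how BicR differed from LNCaP over the 3 treatments. Over all genes 219 were higher in BicR and 395 lower, each with the same sign in 3 of 3 treatments.

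Highest in BicR was FGL1, a fibrinogen-like gene with 38, 59 and 36 counts in BicR and 2, 0 and 0 in LNCaP (adjusted p = 0.00573). ALB, the albumin gene, had 42 counts in BicR ethanol and 1 in LNCaP ethanol, a ratio of 40.3 (6.85 to 1630; adjusted p = 0.00309), and ARHGAP24 had 38 and 1, a ratio of 36.5 (6.16 to 1480; adjusted p = 0.00393). OAS2, which encodes an interferon-induced oligoadenylate synthetase, rose by 5.01 (SE 0.38, adjusted p = 0.000585) and the potassium channel gene KCNJ3 by 4.88 (SE 0.35, adjusted p = 0.000568). CCDC141 passed with adjusted p = 0.00277, but its counts were near 0 in the ethanol and bicalutamide libraries of both lines. Its difference was thus carried by the DHT libraries. Lowest in BicR were OR51E1, an odorant receptor gene active in prostate, at -5.20 (SE 0.38, adjusted p = 0.000568), SEMA6D at -5.12, CNTN5 at -4.06, the small noncoding RNA SNAR-H at -3.90, CREB3L1 at -3.87 and the chemokine gene CXCL12 at -3.53.

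Of 29 interferon response genes 14 rose, 0 fell and 15 did not pass, or 22 and 0 adjusted over the list alone (median 0.88, camera adjusted p = 5.62e-39, adjusted p = 0.582 with an estimated correlation), with RSAD2 at 3.92 and XAF1 at 3.89. Of 40 mitosis genes 8 rose, 0 fell and 32 did not pass, or 32 and 0 adjusted over the list alone (median 1.26, camera adjusted p = 8.6e-20, adjusted p = 0.582 with an estimated correlation), with MKI67 at 1.93, BUB1 at 1.79 and KIF20A at 1.78. The mitosis median was 0.66 without LNCaP ethanol or BicR ethanol. In the androgen-induced list 8 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 0.46, camera adjusted p = 1.12e-08, adjusted p = 0.582 with an estimated correlation); KLK2 rose by 1.78, STEAP4 at 3.20 and SLC38A4 at 2.55 did not pass, and KLK3 fell by 0.91 (adjusted p = 0.0479). Without LNCaP DHT or BicR DHT this median was 0.13, and 0.73 without either bicalutamide library. Luminal markers had 5 rise and 1 fall, or 6 and 1 adjusted over the list alone (median 0.22), with TARP at 2.61. DNA replication had 2 rise, or 3 adjusted over the list alone, with GINS4 at 1.09 (median 0.43, and 0.14 without either ethanol library), nuclear receptor coregulators 2 (0.13), DNA methylation enzymes 1, TET3 at 0.89 (0.27), fatty acid synthesis 1, or 2 adjusted over the list alone (0.15), and DNA repair 0 (0.32). The fatty acid synthesis median was 0.13 between the ethanol, 0.51 between the DHT and -0.02 between the bicalutamide libraries.

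Among the lists lower in BicR, mesenchymal markers had 6 of 18 fall and 0 rise, or 9 and 2 adjusted over the list alone (median -0.75), including COL3A1 at -2.09 and TWIST1 at -2.04. Of the 5 tested immune markers CD74 at -2.62 and HLA-DRA at -1.72 fell (median -0.73, and -0.26 in the bicalutamide libraries). Of 24 p53 targets 4 fell, or 5 adjusted over the list alone, among them SFN at -1.89, BBC3 at -1.49 and the cell cycle inhibitor gene CDKN1A at -1.37 (median -0.27). The p53 median was -0.41 between the ethanol and -0.08 between the DHT libraries, where 12 of the 24 genes were higher in BicR. Steroid synthesis and inactivation had 4 fall and 1 rise, or 5 and 1 adjusted over the list alone, with UGT2B11 at -2.09 and UGT2B15 at -1.74 (median -0.41). Ribosomal proteins had 5 of 67 fall, or 16 adjusted over the list alone, with RPLP0 at -1.26 and RPLP1 at -1.11 (median -0.47, -0.29 without either DHT library and -0.72 without either bicalutamide library; -0.53 between the ethanol, -0.70 between the DHT and -0.04 between the bicalutamide libraries). Oxidative phosphorylation had 1 fall, or 7 adjusted over the list alone, NDUFA1 at -1.14 (median -0.23), hypoxia and glycolysis 1, EGLN3 at -0.89 (-0.30), and the unfolded protein response 1, CREB3L1 (-0.16, but 0.44 between the DHT libraries and -0.95 between the ethanol libraries). In this contrast 17 lists passed camera and 0 passed with an estimated correlation, where adjusted p = 0.582 was the lowest and adjusted p = 0.846, for the unfolded protein response, the highest among those 17.

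By edgeR 0 genes passed when LNCaP bicalutamide, BicR bicalutamide or both were left out (1506 higher and 2102 lower, 1498 and 2117, and 1491 and 2110 at an unadjusted p under 0.05), while DESeq2 called 557 and 933 on all 6 libraries. Between the ethanol libraries alone 364 genes were at least 2-fold higher and 539 lower in BicR, and between the bicalutamide libraries 95 and 176.

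In the ethanol pair TXNIP was 71.4-fold higher in BicR (66.1 to 77.3), OAS2 67.1-fold (40.5 to 120), OASL 12.2-fold (10.9 to 13.6) and FIGN 17.2-fold (13.1 to 23). OR51E1 stood at 0.0291 times the LNCaP level (0.0248 to 0.0339), AGR2 at 0.0295 (0.0247 to 0.035), SLC5A1 at 0.0904 (0.0806 to 0.101) and C1orf158 at 0.0815 (0.0649 to 0.101). Between the bicalutamide libraries TXNIP was 10.6-fold higher (10.3 to 10.9) and AGR2 at 0.38 times (0.313 to 0.458). The mitosis median was 2.16 in ethanol and 0.66 in bicalutamide, the unfolded protein response median -0.95 in ethanol, 0.44 in DHT and -0.07 in bicalutamide, and the interferon response median 1.06 in ethanol, 0.57 in DHT and 1.25 in bicalutamide.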

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

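Of the tests reported here, those chosen only after the result was seen were the tests of a swap with LNCaP DHT, of a response of LNCaP to both compounds, of LNCaP ethanol as the reference, of the opposite directions against bicalutamide, of both lists with the length trend removed, and all 3 tests of the length relation. Responses that ran in opposite directions in the lines were listed wherever a gene passed 2-fold on both sides, or a list lay beyond nearly all of its random lists on both sides; with 1 library per group these differences were not tested.

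Under DHT the log2 difference was -2.73 in LNCaP and 1.86 in BicR for AGR2, -1.07 and 1.01 for C17orf91, 1.05 and -1.37 for the homeobox gene PITX1, -1.25 and 1.02 for SLITRK6, and -1.10 and 1.15 for WIPI1, an autophagy gene. Among the lists under DHT the medians were 0.52 in LNCaP and -0.25 in BicR for DNA replication, -0.94 and 0.49 for the unfolded protein response and secretory pathway, -0.40 and 0.42 for the amino acid stress response, and 0.17 and -0.12 for nuclear-encoded oxidative phosphorylation. Against bicalutamide in place of ethanol, 0 genes were at least 2-fold lower with DHT in LNCaP and higher in BicR, and 1 was the reverse. AGR2 then stood at 0.55 in LNCaP and 1.67 in BicR, and the LNCaP medians were -0.05 for the unfolded protein response and 0.01 for the amino acid stress response, so the opposite directions of AGR2 and of these 2 lists depended on the LNCaP ethanol library. DNA replication stayed opposite, at 0.20 in LNCaP and -0.13 in BicR, and oxidative phosphorylation stood at 0.31 and -0.03. With bicalutamide against ethanol the list medians were 0.32 in LNCaP and -0.12 in BicR for DNA replication, 1.51 and -0.18 for mitosis, -0.53 and 0.08 for the amino acid stress response, and 0.48 and -0.10 for DNA repair.

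The LNCaP ethanol library stood apart, with high unfolded protein response RNA and low mitotic RNA against both treated LNCaP libraries. With a gene length trend removed, the unfolded protein response median of LNCaP bicalutamide against ethanol was -0.92 (spread 0.145), which argues against that trend. Spreads here and below are standard deviations over resamplings of the list's genes, so they cover no variation between cultures. A library of the other line is argued against by the 688 genes called between the lines without the ethanol libraries, 94% of which lay nearer to the other LNCaP libraries, and a swap with LNCaP DHT by KLK3, 3.75-fold higher in the library labelled DHT. The treated LNCaP libraries differed by a median of only -0.05 (spread 0.096) in this list, which a response to both compounds and a stressed, slowly cycling ethanol culture would give alike, so these cannot be told apart with 1 ethanol culture.

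The DHT response of the androgen-induced list was larger in the BicR libraries. Against bicalutamide, without the unusual ethanol library, the BicR median exceeded that of LNCaP by 1.24 (spread 0.119). Against ethanol, with the length trend removed, it did so by 1.18 (spread 0.149). Neither the ethanol reference nor the length trend alone thus accounts for the larger response, and no test removed both at once. Both values rest on 1 DHT library per line, and variation between cultures was not measured. With only 2 lines, the cause cannot be assigned to any 1 of the differences between them.

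Long genes were low in LNCaP DHT relative to LNCaP bicalutamide. Short gene groups such as the ribosomal proteins do not account for it, since the Spearman correlation with length was -0.563 over 13244 genes on no list, and a DHT effect shared by both lines is argued against by -0.0688 in BicR. The LNCaP bicalutamide against ethanol difference also followed length (0.374). RNA integrity or library preparation of single LNCaP libraries may give this, and so may an effect of the treatments in LNCaP; they cannot be told apart with 1 library per treatment.

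For the difference of the lines, the real split of the 6 libraries gave 614 genes, the highest of the other splits gave 0, and only 1 of the 10 splits gave as many. These are too few splits for a share under 0.05. Each other split also mixed the lines, so in its fit the difference of the lines counted as error. Few calls were thus likely there by design, and their 0 gives no background for the 614.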

How the results depend on the processing

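Counts are given as higher and lower, and RLE size factors, removal of the length trend, the authors' RPKM and the bicalutamide or DHT libraries in place of ethanol were chosen after seeing the data. Within a line, counts at 2-fold moved with the pseudocount, the threshold and the scale. For LNCaP DHT (194 and 165) they were 352 and 304 with a pseudocount of 0.1, 78 and 84 with 5, 678 and 734 at 1.5-fold, 59 and 31 at 3-fold and 97 and 76 from RPKM. For BicR DHT (202 and 128) they were 588 and 632 at 1.5-fold, 95 and 29 at 3-fold and 114 and 69 from RPKM, and the lower count was 408 with a pseudocount of 0.1 and 55 with 5. For LNCaP bicalutamide (150 and 211) they were 303 and 337, 45 and 130, 905 and 1102, 38 and 35, and 68 and 114 in the order given for LNCaP DHT. For BicR bicalutamide (0 and 0) they were 15 and 15 with a pseudocount of 0.1, 7 and 15 at 1.5-fold and 2 and 4 from RPKM. For BicR against LNCaP in ethanol (364 and 539) they were 616 and 833, 179 and 307, 1170 and 1777, 142 and 118, and 238 and 260 in that order, and 95 and 176 between the bicalutamide libraries. The correlation of the lines' DHT responses went from 0.116 to 0.189 against bicalutamide. Fewer genes reach a higher threshold by construction; for the other moves the cause was not tested.

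Over both lines, DHT against ethanol (22 and 1) gave 66 and 11 with no count minimum, 75 and 24 with DESeq2, 77 and 24 with DESeq2 and no minimum, and 0 and 0 from the 4 libraries compared. It gave 10 higher with limma-trend at a pseudocount of 5, and 0 lower with limma-trend at a pseudocount of 1 or 5, limma without trend, or a minimum of 100 counts. DHT against bicalutamide (23 and 0) gave 62 and 12 with no minimum, 89 and 33 with DESeq2, 90 and 33 with DESeq2 and no minimum, and 126 and 61 from the 4 libraries compared; it gave 10 higher with limma-trend at 5, 15 higher at 100 counts and 1 lower when quantile-normalized. BicR against LNCaP (219 and 395) gave 503 and 857 with no minimum, 133 and 232 at 100 counts, 557 and 933 with DESeq2 and 573 and 932 with DESeq2 and no minimum; it gave 360 higher when quantile-normalized and 137 higher with no treatment term. Bicalutamide against ethanol stayed at 0 and 0 in each of these. The cause was not tested.

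With each library left out in turn, which leaves a lone library assumed to vary like the others, DHT against ethanol ranged from 0 to 167 higher and 0 to 106 lower, bicalutamide against ethanol from 0 to 102 and 0 to 95, DHT against bicalutamide from 0 to 135 and 0 to 62, and BicR against LNCaP from 0 to 225 and 0 to 470. Without both ethanol libraries the last contrast gave 229 and 459. For the contrasts with DHT and for the lines, the fits at 0 in both directions lacked a bicalutamide library, fits without BicR DHT also gave 0 lower genes for both DHT contrasts, and the highest bicalutamide counts came without BicR ethanol. All counts of lists passing camera stayed within 1.5 times. Values that turned direction were, with the range over libraries left out, UGT2B17 under DHT (-1.68 to 0.62, the highest without BicR DHT, and 0.002 with limma-trend at a pseudocount of 5), TET2 under DHT (-0.67 to 0.076, the highest without LNCaP DHT), NDRG1 between the lines (-0.035 to 1.22, the lowest without either DHT library), and the medians of androgen-repressed genes under DHT (-0.96 to 0.00924, the highest without BicR DHT), the unfolded protein response under bicalutamide (-1.03 to 0.12, the highest without LNCaP ethanol) and mitosis under bicalutamide (-0.14 to 1.71, the lowest without LNCaP ethanol). Of the other values, 991 for named genes kept direction and side of the threshold, 165 lost the threshold and 80 gained it. Of the list medians, 360 held, 5 lost the threshold and 3 moved. For medians over both lines, to hold meant the same direction and side of the threshold. Within a line, where nothing was tested, it meant the same direction and a size within 1.5 times, and other sizes counted as moved. Under the later choices 140 named genes and 64 list medians held by these rules, and 4 list medians moved. Other scalings kept the median difference over all genes within 0.1 of 0, and moved the share of higher genes by over 10 points only for BicR bicalutamide from RPKM (33.3% of its few genes). No paired analysis was possible because each group held 1 library, which leaves no replicate block to add; the fits already match libraries by line and by treatment. Summing rows of one symbol was not run, since 0 names were duplicated. Depth limited the low genes, since CCDC141, NNMT, FGL1 and ALB rest on 0 to 8 counts in their low libraries.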

Other observations

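No test was chosen for this part, and the genes below that fall outside the naming rule were picked after their values were seen. TXNIP, which encodes an inhibitor of thioredoxin that responds to glucose, differed between the lines and between the LNCaP libraries. It stood at 12.9, 261 and 95.8 CPM in LNCaP and at 922, 882 and 1019 CPM in BicR under ethanol, DHT and bicalutamide, and rose by 3.70 (SE 0.74, edgeR adjusted p = 0.0323) in BicR over treatments. The nuclear long noncoding RNA MALAT1 stood at 569, 1232 and 2143 CPM in LNCaP and at 488, 731 and 561 CPM in BicR, with edgeR adjusted p = 0.996 for bicalutamide and 0.91 for DHT against ethanol. HSPA5 stood at 8598 CPM in LNCaP ethanol and at 1245 to 1646 CPM in the other 5 libraries. Under DHT against bicalutamide, ST6GALNAC1, a sialyltransferase gene, rose by 3.07 (SE 0.43, edgeR adjusted p = 0.0398), from 5.27 to 24.6 CPM in LNCaP and from 4.60 to 61.3 CPM in BicR.

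The enzymes and cell types covered by lists without a call under DHT against ethanol had these medians over both lines: 0.04 for steroid synthesis and inactivation (20 genes), -0.00 for nuclear receptor coregulators and pioneer factors (29), 1 of which rose, 0.03 for DNA methylation and hydroxymethylation enzymes (19), 0.02 for neuroendocrine markers (9), -0.14 for mesenchymal and stromal markers (18), -0.33 for immune cell markers (5), -0.10 for the interferon response (29) and -0.09 for hypoxia and glycolysis (31). They were 0.06 for DNA repair (29), 0.02 for oxidative phosphorylation (34), 0.08 for ribosomal proteins (67), -0.00 for the amino acid stress response (30; -0.40 in LNCaP and 0.42 in BicR), -0.24 for the unfolded protein response (36; -0.94 in LNCaP and 0.49 in BicR), -0.05 for microRNA genes and hosts (12) and 0.21 for prostate long noncoding RNAs (8).

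Rows named as microRNA genes numbered 635, of which 552 had 0 counts in every library and 4 passed the count minimum. These were MIR1974 with 32 to 73 counts, MIR1977 with 13 to 27, MIR1978 with 51 to 182 and MIR555 with 8 to 32. MIR21 and MIR29A had 0 counts in all 6 libraries. The sources used here do not say whether the libraries could hold RNAs as short as mature microRNAs. These rows therefore show neither the presence nor the absence of a mature microRNA. Differences between libraries followed relative gene length in some pairs. For BicR against LNCaP the Spearman correlation with length was 0.235 in ethanol, 0.375 in DHT and -0.0433 in bicalutamide. With the length trend removed, 210 of the 219 genes higher in BicR and 386 of the 395 lower still passed edgeR's test. The Spearman correlation across genes was -0.263 for LNCaP DHT against ethanol, 0.374 for LNCaP bicalutamide against ethanol, -0.00169 for BicR DHT against ethanol and 0.124 for BicR bicalutamide against ethanol.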
